A study of Coelastrella tenuitheca with 9 samples.

How the data were processed

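Deposited values were used without new alignment. Per the labels, poly(A) RNA was made into strand-specific libraries with the dUTP method, all in batch 1, from cultures given 0, 20 or 50 mg/L CdCl2 for 7 days. The submitters' processing notes name STAR 2.7.10a, StringTie 2.2.1 and DESeq2 1.34.0. The program that counted reads, its use of strand, the assembly and the annotation release are not given in the sources used here, so reads of overlapping or antisense genes are uncertain.

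The deposited counts are whole numbers per gene and library, for 12605 genes of which 219 had no count in any library. The deposited FPKM values were recomputed from counts, coding length and column total, and 100.0% lay within 1% of the deposited value. Coding lengths were multiples of 3 in 91.85% of genes. The authors' 3 comparison tables hold log2 fold changes, p-values and adjusted p-values for genes under 0.05 only, and the method of adjustment is not given in the sources used here. Per the file headers the other columns of these tables are group means, which matched counts divided by size factors of the 6 libraries compared. A further table of gene positions was not used here. Coordinates are as the deposited table gives them.

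Genes were tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F-test, TMM, group as the only factor, all 9 libraries in 1 fit), and called at a Benjamini-Hochberg adjusted p under 0.05. The filterByExpr step kept 11140 genes and removed 1465. The biological coefficient of variation was 0.139. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 16 lists with at least 5 measured members, and again with an estimated correlation. That second setting also tests on the few residual degrees of freedom of the 9 libraries, so it is much stricter whatever the correlation. A list not called in it is therefore not shown to be unchanged. Other tools were DESeq2 1.42.0, limma on log2 FPKM, and fry. FPKM divides by the column total, so limma on FPKM shares the scaling of library size alone, and a call lost in both is not lost for separate reasons. Counts adjusted over the list alone apply Benjamini-Hochberg to the members of 1 list. Levels of genes with almost no control counts are ratios of summed counts with exact 95% intervals, which cover counting error only.

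Comparisons, tests, 26 gene lists built from product words, alternatives and the rule for naming genes were set before the data were examined. The rule took, per comparison, the 8 genes with the largest rise and the 8 with the largest fall at 10 CPM or more with no overlap between groups, and the 2 members of lowest adjusted p per list. Since only 10.58% of genes have an informative product, 12 described rises and 12 described falls were added after the extent of the annotation was seen, and lists with fewer than 5 measured members were read gene by gene. Genes named outside this rule, or in a comparison other than the one that selected them, were chosen after their values were seen. These include members that do not do what their list's name says, the phosphate carriers, phytochelatin synthase, glucose-6-phosphate dehydrogenase and the ribosome assembly genes in some comparisons. Most named genes are strong calls by this construction, so their stability under other settings is no separate evidence.

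In a self-test, counts were simulated with known changes. Recovery at 1.5-fold was 40.9%, 40.9% and 42.4% for 20 mg/L against control, 50 mg/L against control and 50 against 20 mg/L. At 2-fold it was 78.8%, 81.8% and 77.3%, and at 4-fold 100%, 100% and 98.5%. False calls made up 6.01%, 3.74% and 6.15% of calls. A list shifted on purpose was found in each comparison, and 0 of 15 other lists were called (camera). The simulated genes were drawn independently, whereas the correlation estimated for ribosomal proteins at 20 mg/L against control was 0.662. The self-test therefore does not show how often camera makes false list calls in the real data.

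Replicate numbers were checked for pairing by correlating residuals of libraries with the same number. For 50 mg/L against control these were 0.594, 0.449 and 0.186, which counts as paired by the rule used, although Cd50 3 correlated best with Control 2 (0.395). For 20 mg/L against control they were -0.167, 0.056 and -0.045, and for 50 against 20 mg/L -0.214, 0.132 and -0.218, which is not paired. The main test had no block, because the labels do not say what a replicate number stands for.

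Alternatives added after the data were seen were a block within only the 6 libraries compared, leaving out both libraries displaced on the first component, thinning to the smallest library, limma on log2 CPM with and without removal of the trend on gene length, removal of off-topic list members, and the summed chlorophyll a-b counts under other scalings.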

Results

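Messenger RNA levels were measured by poly(A)-selected, strand-specific RNA sequencing in the freshwater green microalga Coelastrella tenuitheca, strain S93-3. Cells pre-cultured with glucose under continuous light were grown for 7 days with CdCl2 at 0, 20 or 50 mg/L, and 3 libraries were sequenced per group. Libraries are named by group and replicate number (Control 1, Cd20 1, Cd50 1 and so on). The total count assigned to genes per library was 15456743, 12145562 and 12141901 in Control 1 to 3, 11635441, 12692083 and 10801254 in Cd20 1 to 3, and 10457007, 11539763 and 10654565 in Cd50 1 to 3. Levels below are means of CPM (counts scaled to library size) with TMM factors, with the SD of the 3 libraries of a group, and log2 fold changes are given with their standard error (SE) where one is printed. Because the labels do not say that the 3 libraries of a group came from separate cultures, p-values measure only the spread between these samples, which may be technical. Product names are those of the deposited table, present for 19.49% of its 12605 genes and taken from matches to fungal proteins, so each name stands for a similarity and not for a studied algal gene.

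The 3 groups separated from one another. Pearson correlations of log2 CPM were 0.978 to 0.994 within groups and 0.911 to 0.970 between groups. The first principal component held 60.6% of the variance and placed Cd20 (45.0 to 58.1) opposite Cd50 (-52.7 to -17.7). The range of the controls (-29.0 to 12.2) overlapped that of Cd50, since Control 2 lay beyond Cd50 1. The second component, with 25.8%, parted the controls (-39.6 to -35.0) from both cadmium groups (12.2 to 27.8). Control 1 (12.2 on the first component) and Cd50 1 (-17.7) lay nearer to Cd20 than the other libraries of their groups did.

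**Figure D1:**
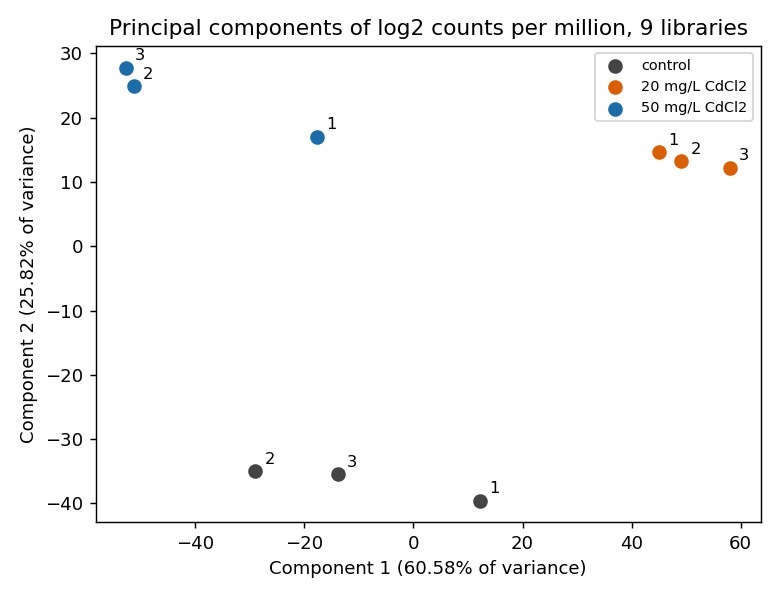
Scores of the 9 libraries on the first 2 principal components of log2 CPM, with each point numbered by replicate and coloured by group. Cd20 lies between 45.0 and 58.1 on the horizontal axis and Cd50 between -52.7 and -17.7.

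After 7 days with 20 mg/L CdCl2, the transcript of a metal carrier fell and several transcripts of glutathione metabolism rose against the untreated cultures. A07895, described as a zinc/iron permease, a carrier family that brings divalent metal ions into cells, went from 809 ± 158 to 121 ± 34.2 CPM (SD, n = 3), a log2 fold change of -2.74 (SE 0.39). A10982, an E1-E2 ATPase, one of the pumps that move ions across membranes at the cost of ATP, rose from 73.1 ± 4.25 to 484 ± 35.5 (log2 fold change 2.73, SE 0.14). Glutamate-cysteine ligase (A01378), which makes the first intermediate of glutathione synthesis, rose from 13.4 ± 1.51 to 29.3 ± 2.64, and the glutathione S-transferases A03303 and A10304, whose family joins glutathione to other compounds, rose by 1.83 and 3.94 on the log2 scale. The phytochelatin synthase-domain gene A02769, of a family that makes metal-binding peptides from glutathione, rose from 61.2 ± 4.90 to 91.5 ± 9.13 CPM (log2 fold change 0.58). In the deposited coordinates, whose assembly is not given in the sources used here, A07895 lies on chromosome 5 from 1198916 to 1201142, A10982 on chromosome 9 from 2950542 to 2959403, A01378 on chromosome 12 from 1069323 to 1073536 and A02769 on chromosome 15 from 1268095 to 1271605. The edgeR adjusted p of these 6 genes ranged from 4.96e-08 to 0.000926.

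The list of glutathione, phytochelatin and metallothionein genes had 7 measured members at 20 mg/L, of which 5 rose, 1 fell and 1 did not pass, and 6 passed when adjusted over the list alone. The member that fell was the glutathione S-transferase A00337 (log2 fold change -0.78), and the one that did not pass was the gamma-glutamyltranspeptidase A05724 (-0.51), which passed with a replicate block (edgeR adjusted p = 0.0393). The glutathione S-transferase A02067 rose by 0.48 with TMM, and its adjusted p in edgeR was 0.0596 when library size alone set the scaling. The list test (camera of limma) gave an adjusted p of 0.00845 with its preset correlation and an adjusted p of 0.635 with an estimated correlation. Without Control 1 the preset value was 0.0699, and without Control 1 and Cd50 1, the libraries displaced from their groups, a setting chosen after the data were seen, 0.151. Among reactive oxygen genes, 4 of 25 rose, 13 fell and 8 did not pass (17 adjusted over the list alone, camera adjusted p = 0.401). The thioredoxin-like fold gene A07320 rose from 343 ± 6.33 to 2477 ± 148 and the 1-Cys peroxiredoxin gene A06230 from 169 ± 22.5 to 424 ± 31.3, both of families that handle thiol redox reactions. Catalase (A05091), which breaks down hydrogen peroxide, fell from 18.9 ± 0.882 to 4.28 ± 1.13, and glutathione reductase (A06116), which regenerates glutathione, fell from 87.9 ± 14.9 to 34.1 ± 4.07.

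At 20 mg/L, 18 of 26 members of the glycolysis and citrate cycle list and 12 of 14 of the flagella list were lower, and 26 of 66 ribosomal protein genes were higher. Glucose-6-phosphate dehydrogenase (A04681), the entry enzyme of the oxidative pentose phosphate pathway, fell from 98.9 ± 13.0 to 21.3 ± 0.89 CPM (log2 fold change -2.21, SE 0.12). Of 26 measured glycolysis and citrate cycle genes, 18 fell, 2 rose and 6 did not pass, with 20 adjusted over the list alone. Malate dehydrogenase (A04353) went from 159.9 ± 14.2 to 63.4 ± 5.02 and the cytosolic aldolase A00135 from 98.3 ± 2.43 to 39.3 ± 5.25. Its list test gave an adjusted p of 8.49e-05 (camera), which became an adjusted p of 0.506 with an estimated correlation. The words that chose this list also took in A01715, a transaldolase of the pentose phosphate pathway, which fell (-1.09, a call lost with an edgeR adjusted p of 0.0502 without Control 2 and 0.0598 without Cd20 3), and A10133, a first-step enzyme of aromatic amino acid synthesis, which rose (0.60). Without the 4 members outside its subject, 17 of 22 fell and 1 rose. Members of the flagella list fell in 12 of 14 cases, with 2 not passing and 12 adjusted over the list alone. The axonemal dynein heavy chains A02273 and A07233, motor proteins of beating flagella, fell by 1.41 and 1.51 on the log2 scale. This list also held the dynein light chain A04672 (-0.57) and a cytoplasmic dynein gene, A05851 (-1.15), which serve transport within the cell as well. Without these and the roadblock-type light chains, 10 of 10 fell. For the flagella list camera gave an adjusted p of 0.000715, and an adjusted p of 0.506 with an estimated correlation.

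Of 66 ribosomal protein genes, 26 rose, 0 fell and 40 did not pass at 20 mg/L, and 23 passed when adjusted over the list alone. Only 16 rose with library size alone and 18 with upper quartile factors. The list median was 0.25 on the log2 scale with TMM and 0.129 with library size alone, where the median of all genes was -0.035 and -0.156. A10100 (a small-subunit protein) was at 0.69 and A05165 (ribosomal protein L1) at 1.65 with TMM. The ribosomal list had a camera adjusted p of 0.000715, against an adjusted p of 0.709 with an estimated correlation. Ribosome assembly genes had no list and were picked by words chosen after the values were seen. Apart from 4 noticed first, 11 of 17 rose and 2 fell. A05852 (guanine nucleotide-binding protein-like 3, a nucleolar GTPase), which those words did not match, rose from 17.6 ± 4.20 to 119 ± 20.9, and of the 4, A03067 (nop7, a ribosome synthesis factor) from 18.2 ± 4.62 to 91.1 ± 16.4 and A08092 (nucleolar GTP-binding protein 2) from 164 ± 51.2 to 545 ± 56.6, whereas A00786 of the 17, described only as ribosome assembly, fell by 1.25 on the log2 scale. Chaperone genes went both ways, with 8 up, 11 down and 13 not passing of 32 (21 adjusted over the list alone, camera adjusted p = 0.925). The HSP90-family gene A06936 rose from 1066 ± 182 to 2181 ± 67.0 and the HSP20-like gene A01849 from 26.6 ± 3.36 to 57.9 ± 5.66, both of families that hold or refold proteins, while the GroES-like genes A03652 (-1.37), A10353 (-1.55) and A00980 (-0.85), named for a domain they share with alcohol dehydrogenases, fell. The edgeR adjusted p of the genes named for rises in ribosomes and chaperones ranged from 3.44e-05 to 0.00285.

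Light-harvesting and sulfate genes went both ways at 20 mg/L, while 5 of 10 cell wall genes fell and 1 rose. Of 13 measured chlorophyll a-b binding genes, the antenna proteins of the photosystems, 6 fell, 4 rose and 3 did not pass (11 adjusted over the list alone, camera adjusted p = 0.507). A00964 went from 93.0 ± 14.7 to 23.4 ± 3.12 and A10888 from 97.9 ± 4.78 to 26.3 ± 4.81, but these copies share one product name and reads may be split between them, so single members are uncertain. Carbonic anhydrase (A10519), which interconverts CO2 and bicarbonate, fell from 129 ± 13.9 to 37.3 ± 5.97. In sulfate uptake and cysteine synthesis, 3 of 6 genes rose and 3 fell, all 6 adjusted over the list alone (camera adjusted p = 0.401), and with library size alone 1 rose. Among those that fell were sulfate adenylyltransferase (A09027, -0.52), which activates sulfate, and a carrier of activated sulfate (A08034, -2.04). Cell wall and polysaccharide genes fell in 5 of 10 cases and rose in 1 (7 adjusted over the list alone, camera adjusted p = 0.173, and with library size alone 0 rises and 6 falls), with glycosyl transferase A07227 at -0.85 and glycoside hydrolase A03217 at -0.68.

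Lists of fewer than 5 measured genes were read gene by gene at 20 mg/L. In metal transport, besides A07895, ferritin-like A04541 fell (-0.66), as did the cation-transporting ATPase A00017 (-0.45), and ferritin-like A01264 was at 0.15 without passing. The call of A00017 was lost in edgeR with an adjusted p of 0.0594 without Control 2, 0.0631 without Control 3 and 0.0833 without Cd20 3. In pigment synthesis, chlorophyll synthase (A03155) fell by 0.81, coproporphyrinogen oxidase-like A07916 rose by 0.54 and porphobilinogen synthase (A00577) rose by 0.50, with porphobilinogen deaminase (A00125) at 0.03. The call of A00577 was lost with an edgeR adjusted p of 0.0807 without Control 1, 0.146 without Control 3, 0.0866 without Cd20 1, 0.106 without Cd20 2 and 0.0648 without Cd20 3, and of 0.142 with library size alone. The beta-carotene ketolase genes, of a family that makes keto-carotenoids, were at -2.56 for A10744, which fell, and 0.36 for A05367, which did not pass. Starch-branching enzyme (A04145) fell from 101 ± 36.1 to 20.4 ± 1.62 CPM, and the Rubisco small subunit (A03462), part of the carbon-fixing enzyme, from 2221 ± 74.0 to 1084 ± 51.2, while fructose-1,6-bisphosphatase (A08799) was at -0.03. For fatty acid synthesis, ketoacyl synthases A07938 (-1.36) and A06457 (-0.64) and acyl carrier protein A08081 (-0.53) fell. The thiolase A09909, an enzyme of fatty acid breakdown that the words also matched, rose by 0.26, a call lost with library size alone (edgeR adjusted p = 0.263) and with an adjusted p of 0.0801 without Control 2, 0.083 without Control 3, 0.192 without Cd20 1 and 0.0611 without Cd20 2. Glutamate synthase A01637 fell by 0.34, a call lost with an edgeR adjusted p of 0.156 without Control 2, 0.0788 without Control 3, 0.0757 without Cd20 1, 0.0768 without Cd20 2 and 0.0809 without Cd20 3. The log2 fold changes of A08811 (glutamate synthase, 0.06), of the genes that the words for ABC transporters matched (A06369 at 0.21, A07164 at 0.11 and A10924 at 0.17), and of A00827 (0.28), an RNA methyltransferase-like gene matched by the words for organelle genes, did not pass. In limma with the length trend removed A01264, A06369 and A10924 passed (adjusted p of 0.0368, 0.0436 and 0.0393). Calls were also lost with upper quartile factors (adjusted p of 0.113 for A00577 and 0.163 for A09909), in limma on FPKM (adjusted p of 0.123 for A00577, 0.0614 for A02067 and 0.267 for A09909), in limma with the length trend removed (adjusted p of 0.0543 for A01637 and 0.0693 for A02793).

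In all, 2650 genes rose and 3026 fell at 20 mg/L among 11140 tested (edgeR quasi-likelihood test, Benjamini-Hochberg), and 504 and 1177 of them changed at least 2-fold. The strongest rises lay in undescribed genes. Novel00414 went from 34.3 ± 7.22 to 3370.0 ± 174 CPM, and A03867, with 7 counts in the 3 control libraries together, was 572-fold higher (95% counting interval 277 to 1424). Undescribed A01165 fell from 51.8 ± 5.50 to 3.87 ± 0.752 and Novel00468 from 82.9 ± 33.8 to 6.16 ± 0.594. The authors' deposited table lists 5607 genes, of which 5237 were also called by edgeR, all in the same direction. The split of calls moved with the scaling: 46.7% of calls were rises with TMM, 39.7% with upper quartile factors and 36.6% with library size alone, which shifted the median of all genes from -0.035 to -0.156 on the log2 scale. In limma on log2 CPM rises were 47.0% of calls, and 54.7% once each library's length trend was removed.

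**Figure D2:**
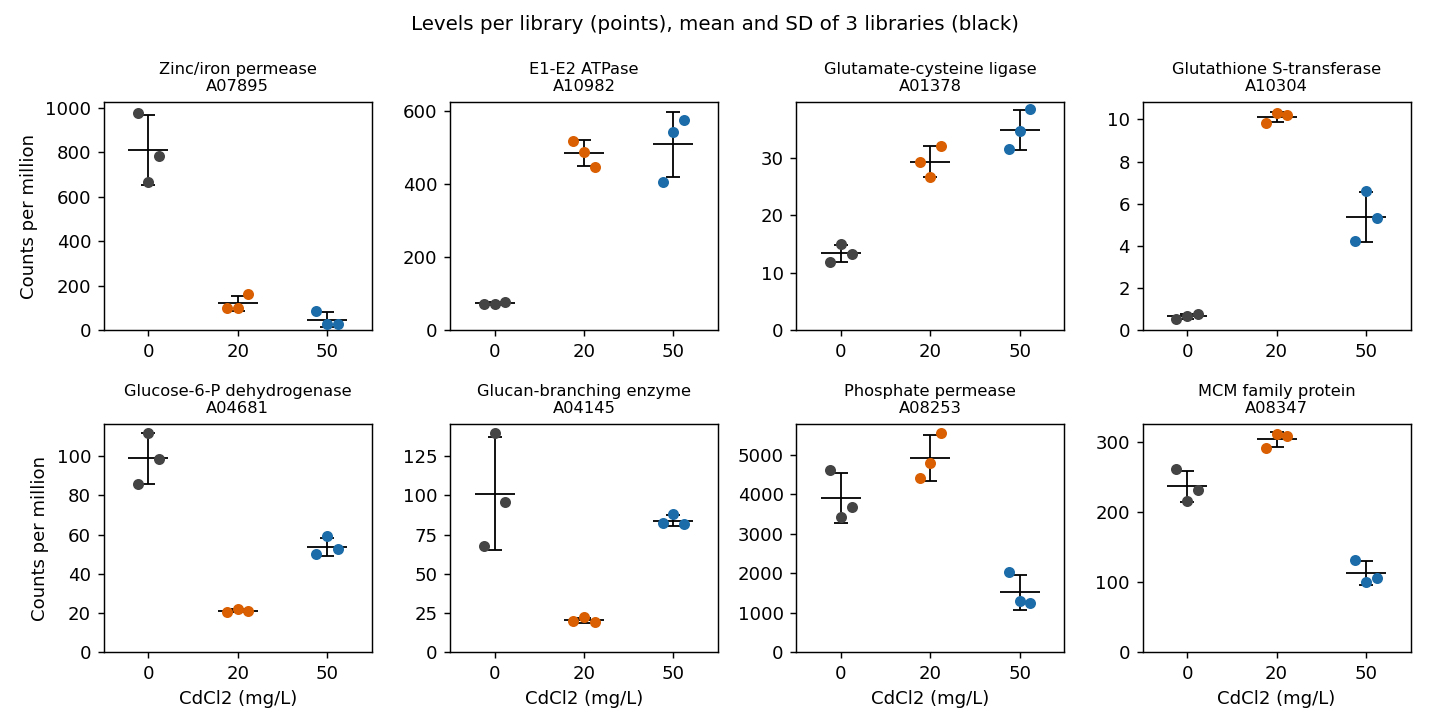
CPM (vertical axes, from 0) of 8 genes at 0, 20 and 50 mg/L CdCl2, with 1 point per library and the mean and SD of 3 libraries in black. The zinc/iron permease A07895 falls from a mean of 809 in controls to 121 and 47.9, while the E1-E2 ATPase A10982 rises from 73.1 to 484 and 508.

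At 50 mg/L CdCl2, compared with no cadmium, the metal carrier transcript was lower, 5 of 7 glutathione genes were higher, and transcripts for phosphate uptake and carotenoid ketolases fell. Zinc/iron permease A07895 went from 809 ± 158 to 47.9 ± 34.9 CPM (SD, n = 3), a log2 fold change of -4.08 (SE 0.42). The phosphate permeases A08253 and A05085, carriers that take up inorganic phosphate, fell from 3908 ± 629 to 1518 ± 439 and from 4811 ± 332 to 2227 ± 467. The ketolase genes A10744 and A05367 fell by 3.78 and 1.00 on the log2 scale, the latter with an edgeR adjusted p of 0.0143, lost at 0.0617 without Control 1, 0.0611 without Cd50 2 and 0.0649 without Cd50 3. E1-E2 ATPase A10982 rose to 508 ± 90.1 from 73.1 ± 4.25. A09495, described as an NADP-binding protein, rose from 32.9 ± 8.51 to 252 ± 49.1, and peptidase M24-domain gene A10377 from 16.5 ± 2.55 to 147 ± 18.0. In the deposited coordinates A08253 lies on chromosome 5 from 3334766 to 3338540, A05085 on chromosome 2 from 1027582 to 1032126, A10744 on chromosome 9 from 1353685 to 1356047 and A09495 on chromosome 7 from 2100550 to 2103290.

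Of the 7 glutathione genes, 5 rose, 0 fell and 2 did not pass at 50 mg/L, with 5 adjusted over the list alone. Glutamate-cysteine ligase A01378 reached 34.8 ± 3.47 CPM, and the glutathione S-transferases A03303, A10304 and A02067 rose by 2.29, 3.04 and 1.18 on the log2 scale. Phytochelatin synthase-domain A02769 rose by 0.32 (edgeR adjusted p = 0.0309), a call lost with an adjusted p of 0.14 without Control 3, 0.0746 without Cd50 2 and 0.0525 without Cd50 3. Here camera gave an adjusted p of 4.13e-05, and an adjusted p of 0.564 with an estimated correlation. Phosphate uptake genes fell in 4 of 5 cases with 1 not passing, and 4 adjusted over the list alone. They included phosphate transporter A03043 (-1.60) and A08132 (-0.76), a triose-phosphate transporter that moves sugar phosphates and not inorganic phosphate alone. The phosphate list had a camera adjusted p of 0.000653, against an adjusted p of 0.564 with an estimated correlation.

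Genes of DNA replication, thiol redox and the citrate cycle were among the described falls at 50 mg/L. The MCM-family genes A07504 and A08347, whose products unwind DNA for replication, fell from 519 ± 115 to 197 ± 68.9 and from 236 ± 22.7 to 113 ± 16.8 CPM. Their list of 30 cell cycle and replication genes went both ways, with 6 up, 7 down and 17 not passing (14 adjusted over the list alone, camera adjusted p = 0.97), and 13 rises and 6 falls with library size alone. Cytoplasmic thioredoxin A02873, a small thiol reductant, fell by 1.51, whereas A07320 and A06230 rose by 2.27 and 0.93. Of 25 reactive oxygen genes, 6 rose, 5 fell and 14 did not pass (11 adjusted over the list alone, camera adjusted p = 0.354), and with library size alone 12 rises and 3 falls. In glycolysis and the citrate cycle 10 of 26 genes fell, 1 rose and 15 did not pass (11 adjusted over the list alone, camera adjusted p = 0.317). Malate dehydrogenase A04353 was at -1.56 and 2-oxoglutarate dehydrogenase A05803 at -0.78, both falls, as was the phosphoglycerate mutase-like A07756 (-0.76), whose role is uncertain. The median of that list was -0.091 with TMM and turned to 0.147 with library size alone, with 6 rises and 5 falls. The median of all genes moved from 0.025 to 0.262 there, so the list median lay below it in both. Cytochrome P450 gene A02478, of a family of oxidising enzymes, fell from 906 ± 52.6 to 348 ± 26.9. The edgeR adjusted p of the falls named in these lines ranged from 1.01e-06 to 0.000547.

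Ribosomal protein genes showed 4 rises, 5 falls and 57 genes not passing of 66 at 50 mg/L, and 0 adjusted over the list alone (edgeR). With library size alone the same list had 29 rises and 0 falls, so no direction is given for it. Members of the flagella list fell in 3 of 14 cases, one being the roadblock-type dynein light chain A05805 (-0.57, a call lost with an edgeR adjusted p of 0.109 without Control 1, 0.0556 without Control 3, 0.0726 without Cd50 2 and 0.118 without Cd50 3, lost with library size alone at an adjusted p of 0.108) of uncertain place, with 11 not passing and 0 adjusted over the list alone, and their median turned from -0.24 to 0.005 with library size alone. The median of all genes moved from 0.025 to 0.262 in that setting, so the flagella median lay below it in both. Chlorophyll a-b binding genes gave 4 rises, 4 falls and 5 not passing of 13 (8 adjusted over the list alone), and 6 rises and 3 falls with library size alone. A10888 fell by 1.35 and A00964 by 1.03, again as copies with uncertain reads. In sulfate uptake and cysteine synthesis 3 of 6 genes fell and 3 did not pass (3 adjusted over the list alone), with sulfate adenylyltransferase A09027 at -0.62. Chaperone genes gave 6 rises, 4 falls and 22 not passing of 32 (10 adjusted over the list alone), against 19 rises and 2 falls with library size alone. Among them were the rise of calreticulin A10050 (0.36), a folding protein of the endoplasmic reticulum, and the fall of small heat shock protein A05773 (-0.59).

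The small lists were also read gene by gene at 50 mg/L. In metal transport only A07895 passed, with A04541 at 0.08, A00017 at 0.06 and A01264 at 0.23. The 3 genes that the words for ABC transporters matched fell, A10924 by 0.41, named for SufB of iron-sulfur cluster assembly, and A06369 and A07164 by 0.36 and 0.25, named for arb1, an ATPase that acts on ribosomes, so that none is known as a transporter. With library size alone none of the 3 passed (edgeR adjusted p of 0.08, 0.198 and 0.885), and calls were lost for A06369 with an adjusted p of 0.0518 without Control 1, 0.0744 without Cd50 2 and 0.0568 without Cd50 3 and for A07164 with an adjusted p of 0.0827 without Control 1, 0.116 without Control 3, 0.0584 without Cd20 1, 0.0578 without Cd20 2, 0.0601 without Cd20 3, 0.161 without Cd50 2 and 0.115 without Cd50 3. Porphobilinogen synthase A00577 rose by 1.07 and chlorophyll synthase A03155 by 0.42, the latter lost with an edgeR adjusted p of 0.0538 without Control 1, 0.0615 without Control 3 and 0.0717 without Cd50 3. A00125 was at 0.03. A07916 fell by 0.25, a call lost with library size alone (edgeR adjusted p = 0.956) and with an adjusted p of 0.108 without Control 1, 0.0854 without Control 3, 0.0569 without Cd20 1, 0.0556 without Cd20 2, 0.0618 without Cd20 3, 0.106 without Cd50 2 and 0.0865 without Cd50 3. Rubisco small subunit A03462 fell by 0.79, and A08799 was at 0.02. Starch-branching A04145 (-0.27) and the fatty acid genes A07938 (0.24), A06457 (0.11), A08081 (-0.16) and A09909 (0.02) did not pass. With library size alone A01264 (0.46), A06457 (0.34), A07938 (0.48), A08799 (0.25) and A09909 (0.26) passed, with edgeR adjusted p of 0.00494, 0.00668, 0.0321, 0.0417 and 0.0397. Calls were also lost with upper quartile factors (adjusted p of 0.305 for A01637, 0.0619 for A05805, 0.0616 for A06369, 0.378 for A07164 and 0.434 for A07916), with no low-count filter (adjusted p of 0.0584 for A01637, 0.0563 for A07164 and 0.0571 for A07916), with only the 6 libraries compared (adjusted p of 0.0936 for A01637, 0.0614 for A05805, 0.0884 for A07164 and 0.0861 for A07916), in limma on FPKM (adjusted p of 0.613 for A01637, 0.084 for A05805, 0.203 for A06369, 0.887 for A07164, 0.92 for A07916 and 0.0756 for A10924). Glutamate synthase A01637 fell by 0.33, a call lost with library size alone (edgeR adjusted p = 0.578) and with an adjusted p of 0.154 without Control 2, 0.0931 without Control 3, 0.0647 without Cd20 1, 0.0646 without Cd20 2, 0.0768 without Cd20 3, 0.077 without Cd50 1, 0.0508 without Cd50 2 and 0.112 without Cd50 3, and A08811 was at -0.11. A00827 rose by 0.55, a call lost with an edgeR adjusted p of 0.0535 without Cd50 3.

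Altogether 1983 genes rose and 2431 fell at 50 mg/L against control (edgeR), 417 and 626 of them at least 2-fold. Novel00414 rose to 1462 ± 40.5 CPM, and A03867 was 281-fold higher than in the controls (95% counting interval 136 to 701). Of 3710 genes in the authors' deposited table, 3658 were also called by edgeR, all in the same direction. Rises made up 44.9% of the calls with TMM, 62.9% with upper quartile factors and 70.9% with library size alone, under which the median of all genes moved from 0.025 to 0.262 on the log2 scale.

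Between the concentrations, all 5 phosphate uptake genes were lower at 50 than at 20 mg/L, while 15 of 26 members of the glycolysis and citrate cycle list and 10 of 14 of the flagella list were higher. Of the 17 ribosome assembly genes, 10 were lower and 3 higher. Phosphate permease A08253 went from 4919.7 ± 579 at 20 mg/L to 1518 ± 439 at 50 mg/L (SD, n = 3), a log2 fold change of -1.70 (SE 0.18). Nucleolar GTP-binding protein A08092 went from 545 ± 56.6 to 137 ± 97.8, nop7 (A03067) from 91.1 ± 16.4 to 24.3 ± 11.7, brx1 (A02270), another ribosome assembly factor, from 65.2 ± 7.96 to 20.3 ± 11.5, and nucleolar RNA helicase A05195 from 258 ± 23.7 to 78.7 ± 24.6, whereas A00786 rose by 1.64 on the log2 scale. Starch-branching enzyme A04145 rose from 20.4 ± 1.62 to 83.9 ± 3.64, glucose-6-phosphate dehydrogenase A04681 from 21.3 ± 0.89 to 53.9 ± 4.67, and carbonic anhydrase A10519 from 37.3 ± 5.97 to 97.1 ± 7.60. Replication gene A08347 fell from 303 ± 10.9 to 113 ± 16.8, and the DnaK chaperone A03630 from 2983 ± 139 to 1412 ± 287. The edgeR adjusted p of these 11 genes ranged from 1.52e-05 to 0.000714.

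All 5 phosphate uptake genes were lower at 50 than at 20 mg/L, and all 5 adjusted over the list alone, with A05085 at -1.41, A03043 at -1.61, A10153 (an SPX-domain gene, of a family that senses phosphate) at -0.59 and the triose-phosphate transporter A08132 at -1.18. That list had a camera adjusted p of 0.000321 and an adjusted p of 0.883 with an estimated correlation. Glycolysis and citrate cycle genes rose in 15 of 26 cases, fell in 4 and did not pass in 7 (20 adjusted over the list alone), with isocitrate dehydrogenase A00711 at 1.42 and fumarate hydratase A03020 at 1.31. Transaldolase A01715 rose as well (1.64), and the falls included A10133 (-0.96) and A07756 (-0.60), a phosphoglycerate mutase-like gene of uncertain role. The isopropylmalate dehydrogenase A07609, of leucine synthesis, rose by 0.29, a call lost with an edgeR adjusted p of 0.0658 without Control 3, 0.149 without Cd20 2, 0.105 without Cd20 3, 0.136 without Cd50 2 and 0.138 without Cd50 3. Without the members outside its subject 13 of 22 rose and 2 fell. Camera gave this list an adjusted p of 0.0398, which was 0.0501 without Control 2, 0.0526 without Control 3, 0.0617 without Cd20 2, 0.0551 without Cd20 3, 0.0513 without Cd50 1 and 0.0602 with a replicate block, and an adjusted p of 0.883 with an estimated correlation. Members of the flagella list rose in 10 of 14 cases and 4 did not pass (10 adjusted over the list alone), among them A02273 (1.00) and A07233 (1.15). Their camera adjusted p was 0.0374, against an adjusted p of 0.883 with an estimated correlation. Of the dynein genes outside flagella, A04672 (0.71) and A05851 (1.15) rose too, and without dyneins outside flagella 8 of 10 rose.

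Ribosomal protein genes fell in 40 of 66 cases, rose in 2 and did not pass in 24 (41 adjusted over the list alone), with A05165 at -1.60 and A10063 at -0.84. Camera gave an adjusted p of 0.00616, and an adjusted p of 0.883 with an estimated correlation. With library size alone 10 members rose, 8 fell, the median turned from -0.287 to 0.066 and camera gave an adjusted p of 0.11. That setting also moved the median of all genes from 0.025 to 0.385, so the list median lay below it in both. Reactive oxygen genes rose in 15 of 25 cases, fell in 5 and did not pass in 5 (20 adjusted over the list alone, and 19 rises and 3 falls with library size alone), with peroxiredoxin A10951 going from 12.7 ± 1.79 to 32.3 ± 2.68 CPM, glutathione reductase A06116 at 1.31 and catalase A05091 at 1.35. Its camera adjusted p of 0.0492 was lost in 11 of 18 other settings (adjusted p of 0.112 with a replicate block, 0.0573 with RLE, 0.0704 without Control 1, 0.0566 without Control 2, 0.0652 without Control 3, 0.109 without Cd20 2, 0.0622 without Cd20 3, 0.0757 without Cd50 1, 0.0913 without both displaced libraries and 0.0529 without off-topic members among them), and was an adjusted p of 0.883 with an estimated correlation. Of 7 glutathione genes 3 rose, 2 fell and 2 did not pass (5 adjusted over the list alone, camera adjusted p = 0.521), and 5 rises and 1 fall with library size alone. A02067 (0.70) and A00337 (0.94) rose, and phytochelatin synthase-domain A02769 fell by 0.26, a call lost with an edgeR adjusted p of 0.206 without Cd20 1, 0.13 without Cd20 2, 0.0874 without Cd50 2 and 0.104 without Cd50 3, with its sign turning to 0.10 with library size alone. In sulfate metabolism A08034 rose by 1.85.

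Gene by gene, the small lists differed between the concentrations as follows. A07895 fell from 121 ± 34.2 to 47.9 ± 34.9 CPM, A04541 rose by 0.75 on the log2 scale and A00017 by 0.51, and A01264 was at 0.07. The arb1-like A06369 and A07164 and SufB-like A10924 fell by 0.57, 0.36 and 0.58, that of A07164 lost with library size alone (edgeR adjusted p = 0.97). Chlorophyll synthase A03155 rose by 1.22 and A00577 by 0.57, A07916 fell by 0.78 and A00125 was at -0.001. Both ketolase genes fell, A05367 by 1.37 and A10744 by 1.22, the latter lost with library size alone (edgeR adjusted p = 0.0785) and with an adjusted p of 0.0821 without Cd20 1, 0.0825 without Cd20 2, 0.101 without Cd50 2 and 0.104 without Cd50 3. Ketoacyl synthases A07938 and A06457 rose by 1.60 and 0.75 and A08081 by 0.37, while A09909 fell by 0.23, a call lost with an edgeR adjusted p of 0.0578 without Control 3, 0.246 without Cd20 1, 0.0572 without Cd20 2, 0.0523 without Cd50 1 and 0.118 without Cd50 2 and with its sign turning to 0.13 with library size alone. Rubisco small subunit A03462 rose by 0.24, a call lost with an edgeR adjusted p of 0.0643 without Control 3, 0.137 without Cd20 2, 0.0704 without Cd20 3 and 0.104 without Cd50 1. The values of A08799 (0.05), A01637 (0.01), A08811 (-0.17) and A00827 (0.26) did not pass. With library size alone A01264 (0.43), A08799 (0.40), A01637 (0.37) and A00827 (0.62) passed, with edgeR adjusted p of 0.00364, 0.00228, 0.0283 and 0.00517. Calls were also lost with upper quartile factors (adjusted p of 0.935 for A02769, 0.247 for A07164, 0.839 for A09909 and 0.0564 for A10744), with only the 6 libraries compared (adjusted p of 0.0833 for A02769 and 0.112 for A09909), in limma on FPKM (adjusted p of 0.436 for A02769, 0.966 for A07164, 0.252 for A09909, 0.0666 for A10153 and 0.0565 for A10744), in DESeq2 (adjusted p of 0.0808 for A03462 and 0.0799 for A07609), with RLE (adjusted p of 0.0648 for A03462 and 0.0626 for A07609), in limma with the length trend removed (adjusted p of 0.353 for A03462 and 0.132 for A07609), with a replicate block (adjusted p of 0.055 for A07609).

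In total 3928 genes were higher and 3865 lower at 50 than at 20 mg/L (edgeR), 1865 and 1038 of them at least 2-fold. The authors' deposited table lists 7430 genes for this comparison, and 7318 of them were called by edgeR in the same direction. Rises were 50.4% of the calls with TMM, 64.5% with upper quartile factors and 70.6% with library size alone, which moved the median of all genes from 0.025 to 0.385. In limma on log2 CPM they were 50.2%, and 46.2% once each library's length trend was removed.

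The lists not described so far did not pass camera in any comparison. Mitochondrial respiration had 2 rises and 5 falls of 12 at 20 mg/L (8 adjusted over the list alone, adjusted p = 0.37), 1 and 1 at 50 mg/L (2, 0.682) and 8 and 1 between them (9, 0.2), with the ATP synthase beta subunit A00554 falling by 0.88 at 20 mg/L. Ubiquitin and proteasome genes had 9 rises and 8 falls of 35 at 20 mg/L (17 adjusted over the list alone, adjusted p = 0.661), 7 and 3 at 50 mg/L (4, 0.429) and 15 and 11 between them (26, 0.705), with polyubiquitin A02498 rising by 0.54 at 20 mg/L. Fatty acid breakdown had 4 rises and 6 falls of 14 at 20 mg/L (10 adjusted over the list alone, adjusted p = 0.53), 0 and 4 at 50 mg/L (4, 0.679) and 7 and 6 between them (13, 0.92). DNA repair had 3 rises and 2 falls of 8 at 20 mg/L (5 adjusted over the list alone, adjusted p = 0.728), 1 and 0 at 50 mg/L (1, 0.566) and 3 and 2 between them (4, 0.829). Autophagy genes had 2 rises and 0 falls of 5 at 20 mg/L (1 adjusted over the list alone, adjusted p = 0.514), 1 and 1 at 50 mg/L (2, 0.747) and 2 and 1 between them (1, 0.829). Phosphate uptake at 20 mg/L had 1 rise, of A10153 (0.42), and no fall (1 adjusted over the list alone, adjusted p = 0.397). At 50 mg/L the camera adjusted p was 0.97 for ribosomal and light-harvesting genes, 0.429 for sulfate genes, 0.566 for chaperones and flagella, and 0.566 for cell wall genes, of which 1 rose and 4 fell. Between the concentrations it was 0.521 for light harvesting (6 rises, 3 falls), chaperones (15, 10) and cell wall genes (4, 1), 0.92 for sulfate genes (2, 3) and 0.21 for the cell cycle (15, 7), which at 20 mg/L had 4 rises, 13 falls and 0.173. Members outside the subject of their list also moved at 20 mg/L, with isopropylmalate synthase A10172, of leucine synthesis, at 0.76, the kinesins A02730 and A07303, named for flagellar kif9, at -0.73 and -0.77, a call lost with an edgeR adjusted p of 0.0788 without Control 3, 0.0609 without Cd20 2 and 0.0517 without Cd20 3, vacuolar ATP synthase subunit A10379 at -0.87 and ubiquitin-like A02793 at -0.49. Rises and falls with library size alone were, at 20 mg/L, respiration 1 and 8, cell cycle 2 and 14, fatty acid breakdown 3 and 7. At 50 mg/L they were respiration 6 and 0, ubiquitin 21 and 1, fatty acid breakdown 4 and 1, autophagy 2 and 0, cell wall 4 and 2, DNA repair 5 and 0. Between the concentrations they were respiration 9 and 0, ubiquitin 24 and 3, fatty acid breakdown 7 and 3, DNA repair 3 and 0, autophagy 4 and 1, light harvesting 7 and 0, chaperones 19 and 4, cell wall 8 and 1, sulfate 3 and 2, cell cycle 22 and 6. Median, mean and test differed in sign for DNA repair and ubiquitin at 20 mg/L, for light harvesting, ribosomal proteins and autophagy at 50 mg/L, and for sulfate genes between the concentrations. Virus, transposon and bacterial marker words matched 2 genes, neither of which was measured well enough to test.

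Changes at the 2 concentrations were compared gene by gene to see how far they ran together. Across 11140 genes, which are not independent replicates, their log2 fold changes had a Pearson r of 0.231 and a covariance of 0.119. Unchanged groups simulated against the same controls gave a mean r of 0.49 and a mean covariance of 0.026 (highest 0.029 in 50 simulations). The observed covariance was 0.092 above that mean. The simulations drew each gene independently, so they lack shifts of a control library that many genes share. Of 2080 genes called at both concentrations, 608 rose at both, against 472 for independent lists, and 790 fell at both, against 660. A further 328 rose at 20 and fell at 50 mg/L (578 for independent lists), and 354 fell at 20 and rose at 50 mg/L (539). A08253 and A05085 were not among these, since only their fall at 50 mg/L passed. A07916 and A03155 were among them, but on calls at 50 mg/L that other settings lost. That of A07916 was lost with library size alone (edgeR adjusted p = 0.956), and that of A03155 without Control 1, Control 3 or Cd50 3. Part of the excess of shared calls may come from the shared controls, which are too few to split. The 682 opposed genes were 180 without Control 3, 282 without Cd50 2, 288 without Cd50 3, 320 without Cd20 2, 333 without Cd20 3, 418 without Cd20 1, 1729 without Cd50 1 and 1079 with library size alone. They were 1055 with a replicate block, 1511 with a block in only the 6 libraries compared and 2079 without both displaced libraries, the last 2 settings chosen after the data were seen. With any 1 library left out, 0 of the genes called in the full fit changed sign in any comparison. The lower counts of opposed genes thus come from lost calls and not from turned directions. Called genes seldom turn sign by their selection, so this is no separate evidence. Without Cd50 1, r was 0.114 and the covariance 0.068.

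**Figure D3:**
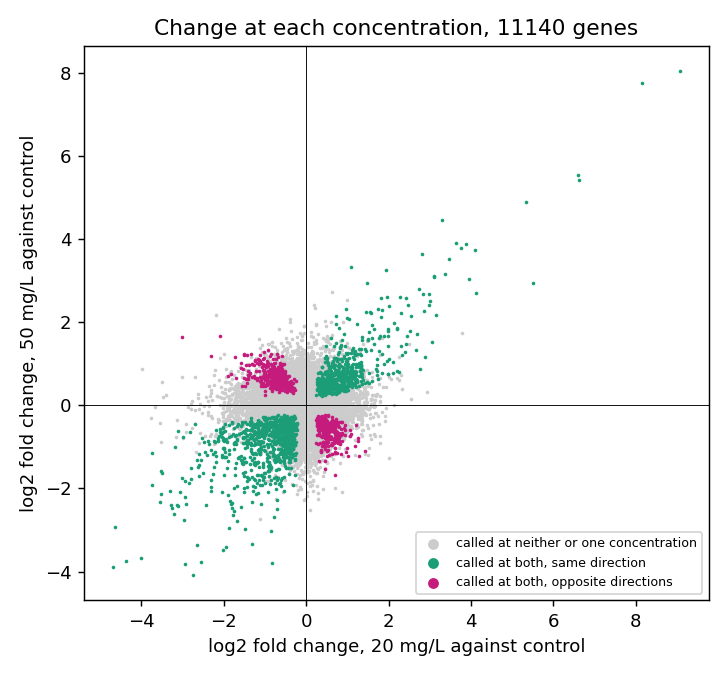
Log2 fold change against control at 20 mg/L (horizontal axis) and at 50 mg/L CdCl2 (vertical axis) for 11140 genes, 1 point per gene. Of the genes called at both concentrations, 1398 lie in the quadrants of equal sign and 682 in those of opposite sign.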

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

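Of the tests used here, both on scaling, the one on differences within a group and the chlorophyll a-b sums under other scalings and relative to the median were chosen after the result was seen, and those on shared controls, gene length, chlorophyll a-b counts summed with TMM and regrouped libraries before. The limma fits that the gene length test used were themselves added after the data were seen.

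The 682 genes called in opposite directions at 20 and 50 mg/L also differed between the concentrations. This follows from how they were selected and is no separate result. A03155 and A07916 were among them, though their calls at 50 mg/L were lost in other settings. Scaling may account for part of the 682 genes and stays open. At the lowest, 26.5% of the genes up at 20 and down at 50 mg/L and 96% of their mirror set stayed, but library size alone and upper quartile factors lower all genes at 20 and raise them at 50 mg/L, which drains the one set and fills the other, so neither value decides. A smooth trend on coding length is an unlikely source for most of them. Of the genes opposed in limma, 86.9% remained so once each library's trend on that length was removed. The length of whole transcripts was not tested. A state that also varies between libraries of one group stays open. The difference of Control 1 from the other controls had an r of 0.724 with that of 20 from 50 mg/L, but Control 1 was picked for lying toward 20 mg/L, so this sign was fixed, and like differences within 20 mg/L had an r of -0.173 to 0.181 with that of control from 50 mg/L, and within 50 mg/L of -0.346 to 0.417 with that of 20 mg/L from control.

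The 608 genes up and 790 down at both concentrations, A10982 and A07895 among them, might owe their match to the shared controls. The covariance of 0.119 lay above the highest of 50 simulated unchanged sets (0.029). Those sets drew each gene independently and so lack shifts that many genes of a library share. They therefore cannot exclude that the shared controls account for it. A response to cadmium at both concentrations remains possible, and the controls were too few to split.

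The chlorophyll a-b binding genes A00964 and A10888 fell at 20 mg/L while other copies rose, which could come from reads shared between near-identical copies. Summed over the family the log2 fold change was -0.131 (SE 0.095, edgeR adjusted p = 0.265) with TMM. It was -0.226 (SE 0.096) with upper quartile factors and -0.255 (SE 0.091) with library size alone, both over 2 SE from 0. Relative to the median of all genes it lay between -0.095 and -0.099 with each of the 4 scalings, within 2 SE of that median, which is what shared reads would give. Taking off the median removes the scaling, so the match between the 4 scalings is no separate evidence. Separate regulation of the copies in opposite directions would give the same and was not excluded.

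Some lists also differed between 50 and 20 mg/L in camera. The adjusted p was 0.0492 for reactive oxygen genes, 0.00616 for ribosomal proteins, 0.0398 for glycolysis and the citrate cycle, 0.000321 for phosphate uptake and 0.0374 for flagella, and an adjusted p of 0.883 for each with an estimated correlation. The call was also lost in 11 of 18 settings for reactive oxygen genes, in 7 of 18 for glycolysis and the citrate cycle, and with library size alone for ribosomal proteins (0.11).

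Each comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05. In edgeR the real split called 5676, 4414 and 7793 genes (20 mg/L against control, 50 mg/L against control, 50 against 20 mg/L) and the highest other split 0 in each, so 1, 1 and 1 split reached the real count. Every other split mixes libraries of both groups, which moves a difference between the groups into the spread. Low counts there thus do not tell what caused the difference. At an unadjusted p under 0.05 the highest other split had 802, 3010 and 523 genes against 6396, 5471 and 8101, and limma called 0 in other splits against 5738, 4325 and 7832. For lists the real split called 4, 2 and 5 and the highest other 4, 4 and 5, so that 3, 6 and 2 of the splits reached the real count. Of the splits at 50 mg/L, 4 part all libraries of the same number.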

How the results depend on the processing

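With an adjusted p under 0.01, 3658 and 2633 genes were called at 20 and 50 mg/L against control, and with a fold change of at least 2, 1681, 1043 and 2903 in the 3 comparisons. Leaving out 1 library gave 4287 to 6383, 3054 to 5614 and 6761 to 8282 genes.

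For lists, camera with an estimated correlation called 0, 0 and 0 in the 3 comparisons, and fry, which does not compare members with other genes, 11, 8 and 9. For cell wall genes at 20 mg/L the estimated correlation (-0.077) lay below the preset, yet the camera adjusted p went from 0.173 to 0.506. The lack of calls with an estimated correlation thus does not by itself show that correlated members made the calls with the preset. With off-topic members removed, an alternative chosen after the data were seen, 1 list was called at 50 mg/L against control and 3 between the concentrations, because the phosphate list then had too few members to test and, between the concentrations, reactive oxygen genes had an adjusted p of 0.0529. Leaving out 1 library gave 3 to 4, 2 to 2 and 3 to 5 lists.

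The r of 0.231 between the changes ranged from 0.114 without Cd50 1 to 0.3 without Control 1, and was 0.162 without both displaced libraries, chosen after the data were seen. The cause was not tested.

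With a replicate block the counts were 6068, 4824 and 7944 genes and 4, 2 and 3 lists, and r was 0.226. A block in only the 6 libraries compared, chosen after the data were seen, gave 5705, 6047 and 7243.

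Of 188 named gene results, 139 kept call and direction in all 11 alternatives. Among these alternatives, library size alone and limma on FPKM share 1 scaling and are not separate checks. The fits with 1 library left out counted as 1 alternative, judged by a turned sign or else by the highest adjusted p. A result that had not passed could therefore not be recorded as passing with 1 library left out. Signs turned, mostly for values near 0 that had not passed, as follows. A00017 was -0.022 with 1 library left out at 50 mg/L. A00125 was -0.089 with library size alone, -0.057 with upper quartile factors, -0.087 with limma on FPKM, -0.02 with libraries thinned to one depth and -0.073 with 1 library left out at 20 mg/L. A00125 was -0.079 with 1 library left out at 50 mg/L. A00125 was 0.364 with library size alone, 0.256 with upper quartile factors, 0.045 with only the 6 libraries compared, 0.331 with limma on FPKM, 0.035 with libraries thinned to one depth and 0.004 with 1 library left out between the concentrations. A01264 was -0.04 with length trend removed between the concentrations. A01637 was -0.029 with DESeq2, -0.025 with RLE, -0.001 with replicate block, -0.032 with length trend removed and -0.065 with 1 library left out between the concentrations. A02769 was 0.095 with library size alone and 0.097 with limma on FPKM between the concentrations. A04145 was 0.026 with limma on FPKM and 0.036 with 1 library left out at 50 mg/L. A07164 was -0.012 with library size alone and -0.012 with limma on FPKM at 20 mg/L. A08081 was 0.073 with library size alone and 0.074 with limma on FPKM at 50 mg/L. A08799 was 0.081 with length trend removed and 0.009 with 1 library left out at 20 mg/L. A08799 was -0.005 with 1 library left out at 50 mg/L. A08799 was -0.037 with length trend removed and -0.042 with 1 library left out between the concentrations. A08811 was -0.067 with library size alone, -0.038 with upper quartile factors and -0.061 with limma on FPKM at 20 mg/L. A08811 was 0.126 with library size alone, 0.05 with upper quartile factors and 0.125 with limma on FPKM at 50 mg/L. A08811 was 0.192 with library size alone, 0.087 with upper quartile factors and 0.186 with limma on FPKM between the concentrations. A09909 was 0.129 with library size alone, 0.023 with upper quartile factors and 0.125 with limma on FPKM between the concentrations. These settings also moved the median of all genes between the concentrations, from 0.025 to 0.385, 0.28 and 0.328 in that order. Sign turns in them thus go with a shift of all genes and are not particular to the genes named. The cause of the other turns was not tested.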

Other observations

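Genes of ribosomal RNA processing, which no list covered, were chosen for naming here after their values were seen. PNO1 (A07533), which matures the small subunit, rose by 1.42 on the log2 scale at 20 mg/L and fell by 1.60 from 20 to 50 mg/L. The rpf2 gene (A07627), a large-subunit assembly factor, fell by 1.49 from 20 to 50 mg/L, and the methyltransferase nop2 (A04256) rose by 1.31 at 20 mg/L and fell by 1.55 between the concentrations. The 25S methyltransferase gene A02782 rose at both concentrations (1.22 and 0.91). The methyltransferase-like A05580 rose by 1.33 from 20 to 50 mg/L. Among 137 words in product names tested with camera, those given here are some that passed. At 20 mg/L these were rrna (9 of 10 genes up) and ribosomal (30 of 73 up), both with an adjusted p of 0.00363. Dehydrogenase (35 of 60 down), axonemal (7 of 7 down) and dynein (10 of 12 down) each had 0.00803. At 50 mg/L they were fold (4 of 6 up, 0.0042) and permease (5 of 6 down, 0.00645). With an estimated correlation the words given at 20 mg/L had an adjusted p of 0.915 and those at 50 mg/L 0.992.

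The test on ribosome assembly was written after the result was seen, and the tests on neighbours and on loci with an identifier outside the A series before.

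Ribosome assembly genes may move as a group between the concentrations. With the members that raised the idea, such as A08092 and A03067, left out, 17 others gave a camera p of 0.138 with an estimated correlation (0.0451 with the preset), with 10 falls and 3 rises. At 20 mg/L against control, where 11 rose and 2 fell (median 0.553), the p was 0.0364 (0.00167 with the preset). These still include genes named above such as A07533, so that the value at 20 mg/L is no separate evidence, and a p that misses the threshold shows no absence of a shared change, which leaves the idea open.

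Genes changed at least 2-fold the same way at both concentrations may lie beside each other. The set of 264 genes held 17 neighbouring pairs, none overlapping, against a mean of 3.28 and a highest value of 12 in 10000 random sets (permutation p = 1e-04, the smallest these can give). One member of such a pair is A09495. The median gap was 1198 bases in these pairs and 1942 between all neighbours. Gaps in these pairs ran from 46 to 13325 bases. Neighbours were taken among tested genes only, and the random sets were not matched on expression. Shared promoters or read-through transcripts could both yield such pairs. Neither these nor other sources were told apart.

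Loci with an identifier outside the A series could be over-represented in that set, but 41 were found against a mean of 35.75 in matched random sets (permutation p = 0.195), so an excess was not shown.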
